A study of Mus musculus with 25 samples.

How the data were processed

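The authors deposited 2 tables of gene counts, 1 for the hepatocyte libraries and 1 for the immune cell libraries, and every value in the report derives from these raw counts. Per the submitters' processing notes, reads were aligned to mm10 with STAR, counted per gene with HTSeq and compared with DESeq2. The versions of STAR, HTSeq and DESeq2 used by the submitters are not given in the sources used here. Per the sample labels, the liver was perfused, cells were sorted with a BD FACSAriaIII, RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit from 1 ug of RNA. Reads were not realigned, so mapping and the choice of annotation could not be checked. All columns were matched to a sample, with 0 columns left over.

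The hepatocyte table had 18669 genes, of which 18626 had a symbol, and the lowest total over the libraries was 10 counts, so rarer genes were absent from it. The immune table had 51913 genes, 51633 with a symbol, and 7434 had 0 counts. Symbols and coordinates came from GENCODE M21 (GRCm38), and 48 hepatocyte and 422 immune identifiers had no unique symbol. Both tables also held an EGFP transgene, which was kept out of library sizes and tests.

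Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each table was fitted as a whole with 1 term per group and no other covariate, by edgeR quasi-likelihood F tests with TMM scaling, after filterByExpr by group. This left 14339 hepatocyte genes (8 residual degrees of freedom, common biological coefficient of variation 0.313) and 27759 immune genes (6 degrees of freedom, 1.00). The groups share 1 estimate of spread because several have only 2 libraries. A gene counted as called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. Adjusted p-values of single genes in the report are from edgeR unless another tool is named. Levels are CPM on TMM-scaled library sizes, given as mean and SD over libraries, and the SE of a log2 fold change is its absolute value divided by the square root of F, which is approximate. A gene with no count in a group is given as a fold bound with a floor of 3 counts over that group, and a gene with 1 to 3 counts as a ratio with a 95% counting interval. These intervals and floors cover counting error only and leave out the spread between animals.

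The gene lists, comparisons, tests and alternatives were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all list and comparison pairs of 1 table, and needed at least 3 measured members. An estimated correlation and the rotation test fry were the alternatives. Of 72 hepatocyte list calls (42 up and 30 down), 5 held with an estimated correlation: acute phase genes in IL-6 against GFP, in IL-6 STAT3KO against IL-6 and in the interaction, and interferon targets in IL-6 STAT3KO against GFP and in the interaction. Of 41 immune list calls (31 up and 10 down), 4 held: Kupffer cell markers in macrophages against other cells and cell cycle genes in all 3 immune comparisons. Of 205 list medians, 32 had a member absent from a group, 13 changed when such members were set to their bound, and the largest change was 3.89.

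Genes were named by a rule fixed in advance. It took Stat3, Il6, Il6ra, Il6st, Socs3 and Sox9 in each hepatocyte comparison and the gp130 cytokines in each immune comparison, whatever their result. It then took the 5 higher and 5 lower genes with the largest log2 fold change among called genes with a mean of at least 20 CPM, no overlap between libraries of the compared groups and a symbol other than a predicted gene or antigen receptor segment. For the interaction, overlap was judged on differences between libraries. Up to 4 members per list with the smallest adjusted p were added, or 2 where none passed. Some of the genes so selected are not reported here. Saa2, Lbp, Fgl1, C4b and Serping1 in DDC STAT3KO against DDC, library values of Spp1 and Clec4f there, library values of Alb, and Il1a, Il1b, Il1rn and Bmp2 in macrophages against single cell types were chosen after their values were seen.

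The raised sets were the genes called higher with a log2 fold change over 1. For contrasts that share libraries, 20 simulations of unchanged groups gave the correlation and covariance that sharing alone produces. The alternatives fixed in advance were median-of-ratios factors, no filter on low counts, the replicate number as a block, a fit of only the compared groups, DESeq2, a log2 fold change over 1, and each library left out in turn. Leaving out the T cell libraries, or IL-6 replicate 3 together with DDC STAT3KO replicate 3, was chosen after seeing the data, as was the use of 1 GFP library for each of the IL-6 and DDC contrasts.

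The code was tried on simulated counts with the spread of these data, with 100 genes changed 2-fold and 100 4-fold. It called 10 and 55 of them in IL-6 against GFP, 18 and 67 in IL-6 STAT3KO against IL-6, and 16 and 55 in DDC STAT3KO against DDC, with 1 to 5 false calls. In DDC against normal macrophages and in the monocyte comparison it called 0 of either, with 3 and 0 false calls. Such a change would be missed there.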

Results

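Gene expression was measured by bulk RNA sequencing in cells sorted from mouse liver, in 13 hepatocyte libraries of 5 groups and 12 immune cell libraries of 6 groups. The hepatocytes, the main epithelial cells of the liver, came from wild-type mice 1 week after hydrodynamic tail vein injection, which drives plasmid DNA into the liver, of a GFP plasmid (n = 2) or an IL-6 plasmid (n = 3). A further group held hepatocytes of Stat3-floxed mice 2 weeks after AAV-TBG-Cre and 1 week after the IL-6 plasmid (IL-6 STAT3KO, n = 3). AAV-TBG-Cre is a viral vector that expresses Cre recombinase from a hepatocyte promoter, which deletes the floxed gene in hepatocytes. The last hepatocyte groups came from Stat3-floxed mice after 1 week of DDC diet, a feed that blocks haem synthesis and injures bile ducts, with AAV-TBG-GFP (DDC, n = 2) or AAV-TBG-Cre (DDC STAT3KO, n = 3). The immune cells came from wild-type mice after 1 week of DDC diet and were macrophages, T cells, neutrophils and Ly6C-low and Ly6C-high monocytes, with macrophages of mice on a normal diet beside them (n = 2 each). The series addresses signalling from macrophages to injured hepatocytes through IL-6, its receptor subunit gp130 and STAT3.

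Depth is given in order of replicate number as 1e6 counts per library. The hepatocyte libraries held 16.0 and 14.7 in the GFP plasmid group, 16.5, 18.4 and 18.4 in the IL-6 group, and 16.2, 16.5 and 17.5 in the IL-6 STAT3KO group. They held 17.1 and 18.5 in the DDC group and 18.2, 18.0 and 13.6 in the DDC STAT3KO group. The immune libraries held 10.2 and 12.9 for DDC macrophages, 7.13 and 11.0 for macrophages on normal diet, and 11.8 and 10.6 for T cells. They held 8.92 and 3.82 for neutrophils, 10.3 and 10.9 for Ly6C-low monocytes, and 10.3 and 8.88 for Ly6C-high monocytes. Replicates of 1 hepatocyte group correlated at r = 0.937 to 0.983 across genes, while the immune pairs ranged from 0.666 for neutrophils to 0.919 for DDC macrophages. Genes are not independent replicates, so these values carry no p-value. A single predicted gene, Gm10800, took 19.0% of the counts in neutrophil replicate 2 and 8.85% in Ly6C-high monocyte replicate 1. The labels do not state that replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

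Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540, reverse strand, GRCm38) encodes the transcription factor whose gene was floxed. Its level was 108.6 and 98.9 counts per 1e6 counts (CPM) in the GFP plasmid libraries, 339.7, 351.1 and 423.9 CPM in the IL-6 libraries, and 115.8, 96.0 and 115.7 CPM in the IL-6 STAT3KO libraries. The DDC libraries held 150.1 and 112.0 CPM, and the DDC STAT3KO libraries 62.1, 56.3 and 87.3 CPM. The counts sum reads over the whole gene and the labels do not name the deleted exons, so the reads left in the STAT3KO libraries do not show an intact transcript. Nor do they show the deletion in the IL-6 STAT3KO libraries, which held as much Stat3 as the GFP plasmid libraries. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981, forward strand), which the plasmid also carries, stood at 4.89, 3.21 and 350.9 CPM in the IL-6 libraries and at 0.743, 0.559 and 1.05 CPM in the IL-6 STAT3KO libraries, against 0 and 0.0688 CPM with the GFP plasmid. Socs3 (chromosome 11, 117966079 to 117970047, reverse strand), a feedback inhibitor that STAT3 induces, stood at 11.7 and 11.97 CPM with the GFP plasmid, 215.8 to 292.1 CPM with the IL-6 plasmid and 3.97 to 6.69 CPM in the IL-6 STAT3KO libraries.

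**Figure D1:**
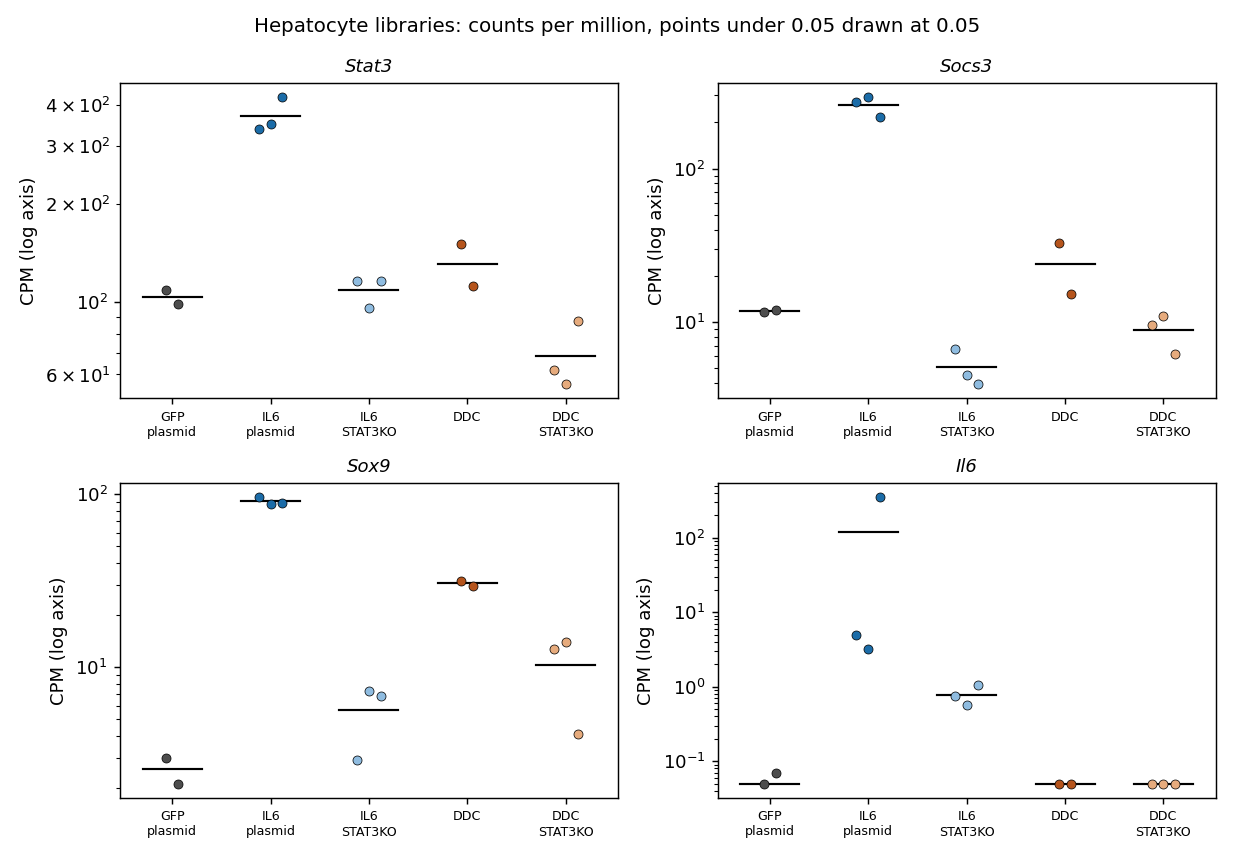
CPM (log axis) of Stat3, Socs3, Sox9 and Il6 in each hepatocyte library by group, with the group mean as a line and points under 0.05 CPM drawn at 0.05. The IL-6 libraries held 215.8 to 292.1 CPM of Socs3 and the IL-6 STAT3KO libraries 3.97 to 6.69 CPM, while IL-6 replicate 3 alone held 350.9 CPM of Il6.

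Hepatocytes of mice given the IL-6 plasmid were compared with those given the GFP plasmid, to describe the response to IL-6 in wild-type liver. Acute phase genes, which encode plasma proteins of the systemic inflammatory response, rose most broadly: 27 of 31 measured members were higher and none was lower (27 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 3.91. Serpina3n, a protease inhibitor, rose from 464 ± 78.6 (SD, n = 2) to 5931 ± 249 CPM (n = 3), and Hpx, the haem-binding haemopexin, from 3367 ± 55.8 to 61114 ± 1527 CPM. Lbp, which binds bacterial lipopolysaccharide, and the metalloreductase Steap4 rose by 3.14 ± 0.27 and 4.32 ± 0.38 (log2 fold change ± SE, the form used from here on). In the other direction, 18 of 27 cytochrome P450 and conjugation genes and 13 of 19 bile acid genes were lower, though neither list was called with an estimated correlation (camera adjusted p = 0.197 for each). Slco1a1, an organic anion importer, fell by 8.58 ± 0.52, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 6.92 ± 1.01.

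In all, 1964 genes were higher and 1755 lower of 14339 tested (edgeR, adjusted p under 0.05). Mitochondrial genes took 2.33%, 2.05% and 2.76% of the counts in the IL-6 libraries, 5.56% and 5.60% in the GFP plasmid libraries and 4.16% to 5.92% in the IL-6 STAT3KO libraries. Whether this reflects the state of the cells or the quality of the libraries was not tested. Stat3 itself rose by 1.84 ± 0.24 (adjusted p = 0.000281) and Socs3 by 4.46 ± 0.40 (adjusted p = 2.89e-05). Sox9, a transcription factor of bile duct and progenitor cells, rose from 2.57 ± 0.62 to 90.7 ± 4.71 CPM (log2 fold change 5.13 ± 0.55, adjusted p = 8.17e-05). The receptor genes Il6ra (-0.60 ± 0.46, adjusted p = 0.367) and Il6st, which encodes gp130 (0.28 ± 0.22, adjusted p = 0.381), did not pass. Il6 had 1 count in the GFP libraries together, and its ratio was 3852 (95% counting interval 691.1 to 152200, adjusted p = 0.0179, 0.0625 with only these groups in the fit). Most of its reads came from IL-6 replicate 3, without which the log2 fold change was 6.635 (adjusted p = 0.00179). Among the most raised genes, the antimicrobial lectin Reg3g was at least 11020-fold higher, as no GFP library held a count. Its paralog Reg3b, with 1 count in the GFP libraries, had a ratio of 69790 (12530 to 2757000), and the protease inhibitor A2m, with 3 counts, a ratio of 48800 (16700 to 236600). Ly6d and Acpp, an acid phosphatase, were at least 1388-fold and 1343-fold higher. The most lowered genes were Car3, a carbonic anhydrase (-12.66 ± 1.26), Ces1f, a carboxylesterase (-10.13 ± 0.89), Inmt, a methyltransferase (-9.78 ± 1.05), Hsd3b5, a steroid dehydrogenase (-9.45 ± 1.00), and Upp2, a uridine phosphorylase (-8.60 ± 1.02), with adjusted p of 0.000151 or less.

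Among the fixed gene lists, 18 of 27 cytochrome P450 and conjugation genes were lower and 1 higher (20 and 1 when adjusted over the list alone), including Ugt2b1 (-6.07 ± 0.43), Cyp2f2 (-4.61 ± 0.36), Cyp4f14 (-2.90 ± 0.29) and Ces1d (-6.74 ± 0.73). The cytochrome P450 list had camera adjusted p = 7.68e-16 with the preset. Bile acid synthesis and transport had 13 of 19 lower and 2 higher (14 and 2 when adjusted over the list alone), among them Slco1a4 (-5.14 ± 0.62) and Cyp27a1 (-2.20 ± 0.27). The bile acid list had camera adjusted p = 1.64e-07 with the preset. Of 26 amino acid, urea and glucose genes, 17 were lower and 1 higher (18 and 1 when adjusted over the list alone), with the glucose transporter Slc2a2 at -5.58 ± 0.48. Otc of the urea cycle (-2.48 ± 0.26) and Hgd of tyrosine breakdown (-1.66 ± 0.21) were lower as well, and camera gave adjusted p = 2.01e-11 for the list, with adjusted p = 0.252 with an estimated correlation. NRF2 targets, which include glutathione enzymes, had 12 of 23 lower and 2 higher (12 and 3 when adjusted over the list alone), including Gsta2 (-7.67 ± 0.68), Gstm1 (-3.42 ± 0.49), Cyp2a5 (-4.45 ± 0.68) and Gstm4 (-2.02 ± 0.33). The NRF2 target list had camera adjusted p = 0.00114, and adjusted p = 0.554 with an estimated correlation. Fatty acid oxidation had 8 of 23 lower and 2 higher (9 and 2 when adjusted over the list alone), with Acaa1b at -4.18 ± 0.61 and Fabp1 at -3.70 ± 0.65. The fatty acid oxidation list had camera adjusted p = 0.00194, and adjusted p = 0.704 with an estimated correlation. Hepatocyte transcription factors had 6 of 20 lower and 1 higher in both ways of adjusting, with Klf15 (-1.89 ± 0.31), Nr1i3 (-2.37 ± 0.42), Foxa1 (-1.30 ± 0.26) and Cebpa (-1.61 ± 0.33) lower. The transcription factor list had camera adjusted p = 0.0448, and adjusted p = 0.568 with an estimated correlation.

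Progenitor and biliary genes had 9 of 16 higher and 1 lower (12 and 1 when adjusted over the list alone), a median of 3.36. The progenitor list had camera adjusted p = 1.73e-05, and adjusted p = 0.419 with an estimated correlation. Besides Sox9, these were led by the receptor Tnfrsf12a (3.19 ± 0.36), the secreted phosphoprotein Spp1 (11.32 ± 2.06) and Anxa2 (3.45 ± 0.69). Of 27 IL-6 and STAT3 signalling genes, 8 were higher and 1 lower in both ways of adjusting, including Osmr, a receptor of the same cytokine family (5.62 ± 0.57), and Socs1 (6.61 ± 0.69). The IL-6 signalling list had camera adjusted p = 0.00213, and adjusted p = 0.288 with an estimated correlation. Cell cycle genes had 10 of 32 higher and none lower (25 and none when adjusted over the list alone), such as the replication factors Mcm2 (2.17 ± 0.57) and Mcm6 (2.46 ± 0.72). The cell cycle list had camera adjusted p = 3.12e-05, and adjusted p = 0.704 with an estimated correlation. The unfolded protein response had 6 of 23 higher and 1 lower (9 and 1 when adjusted over the list alone), with Xbp1 (1.28 ± 0.25), Pdia4 (1.47 ± 0.29) and Calr (1.28 ± 0.26) higher and Herpud1 (-2.04 ± 0.46) lower. That response had camera adjusted p = 0.0246, and adjusted p = 0.621 with an estimated correlation. No call by camera was made for YAP targets (4 of 16 higher, Tead1 by 2.83 ± 0.35, adjusted p = 0.0987), haem and porphyrin metabolism (2 of 18 higher and 4 lower, adjusted p = 0.17), or sterol and fatty acid synthesis (1 of 24 higher and 1 lower, adjusted p = 0.802). None was made either for immediate early genes (3 of 17 higher and 3 lower, median -0.19 but mean 0.45, adjusted p = 0.508) or interferon targets (3 of 33 higher and 3 lower, median 0.24 but mean -0.01, adjusted p = 0.999).

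Markers of other cells moved with the plasmid as well. Neutrophil markers had 5 of 6 measured members higher, S100a8 and S100a9 at least 23.3-fold and 24.0-fold, though at means of 2.44 ± 1.86 and 2.51 ± 2.03 CPM (camera adjusted p = 0.0161, adjusted p = 0.612 with an estimated correlation). Their median log2 fold change was 7.91 as fitted and 4.02 with members absent from a group set to their bound. Kupffer cell markers had 7 of 14 higher and 3 lower (adjusted p = 0.0718), with Cd163 at 3.12 ± 0.81 and Slc40a1, which hepatocytes also express, at -1.48 ± 0.27. General macrophage markers had 2 of 12 higher and 1 lower (adjusted p = 0.259), cholangiocyte markers 4 of 7 higher (adjusted p = 0.127), T cell markers 1 of 3 higher (Cd28, ratio 731.1, 130.9 to 28900, adjusted p = 0.105 for the list) and dendritic cell markers 1 of 7 higher (adjusted p = 0.916). Sinusoidal endothelial (12 measured, adjusted p = 0.251), stellate (13 measured, adjusted p = 0.411) and B cell markers (3 measured, adjusted p = 0.278) had none past the threshold, and hepatocyte markers had 3 of 17 higher and 6 lower (adjusted p = 0.304).

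The count of 3719 genes rested on both control libraries, with 1777 genes without GFP replicate 1 and 1702 without replicate 2. IL-6 replicate 3, with 350.9 CPM of Il6 against 4.89 and 3.21 CPM in the other IL-6 libraries, gave 3472 genes when left out alone. It also stood apart in Alb, which took 0.557% of its counts against 6.45% and 2.99% in the other IL-6 libraries. Left out together with DDC STAT3KO replicate 3, a choice made after seeing the data, it gave 4365.

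**Figure D2:**
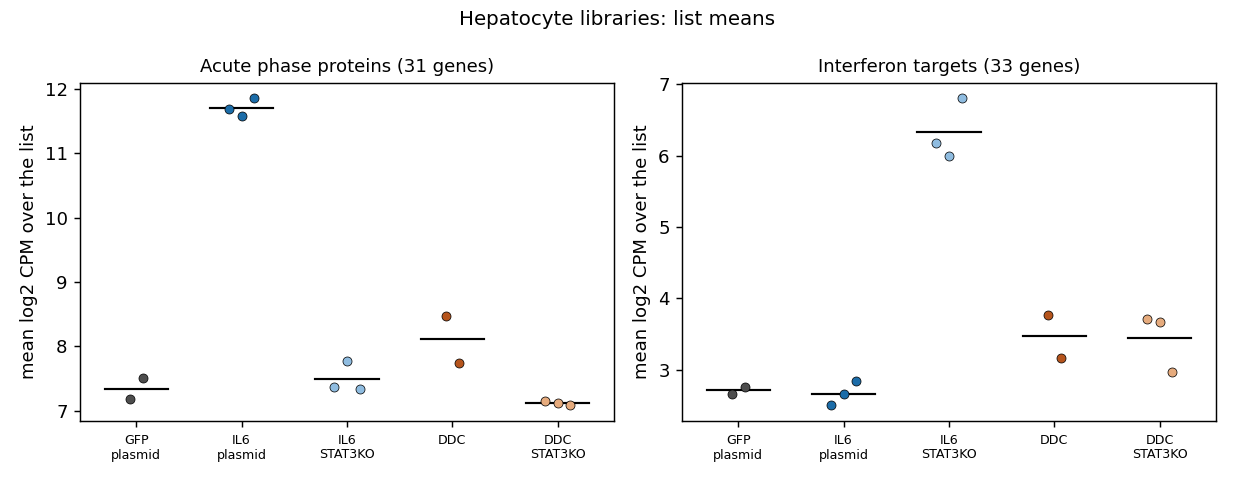
Mean log2 CPM over the members of the acute phase list (31 genes) and the interferon target list (33 genes) in each hepatocyte library by group, with the group mean as a line. Acute phase means were highest in the IL-6 group (11.71 ± 0.14, SD, n = 3), and interferon target means were highest in the IL-6 STAT3KO group (6.33 ± 0.42, n = 3).

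The IL-6 STAT3KO hepatocytes were compared with the IL-6 hepatocytes to describe what the IL-6 plasmid does in floxed mice given AAV-TBG-Cre. Both groups received the plasmid, but genotype, AAV vector and Il6 level differed together between them. Acute phase genes were lower, with 28 of 31 down and none up (28 lower and 1 higher when adjusted over the list alone) and a median of -3.68. Serpina3n was at 532 ± 82.1 against 5931 ± 249 CPM (SD, n = 3 each), Itih3, a hyaluronan-binding plasma protein, at -4.08 ± 0.29, the fibrinogen chain Fgb at -3.55 ± 0.29 and Lbp at -2.69 ± 0.22. Of 33 interferon targets, 31 were up and none down (32 and none when adjusted over the list alone), although the list was not called with an estimated correlation (camera adjusted p = 0.0551). The interferon-induced GTPase Igtp stood at 875 ± 252 against 19.5 ± 5.06 CPM.

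The edgeR test called 1866 genes higher and 1915 lower. Stat3 was at -1.77 ± 0.21 (adjusted p = 0.000100), Socs3 at -5.68 ± 0.36 (adjusted p = 2.16e-06), Sox9 at -3.99 ± 0.43 (adjusted p = 5.25e-05) and Il6 at -7.24 ± 1.76 (adjusted p = 0.0128, 0.784 ± 0.248 against 120 ± 200 CPM). Without IL-6 replicate 3, Il6 was at -2.34 (adjusted p = 0.0199). Il6ra (0.33 ± 0.42, adjusted p = 0.610) and Il6st (-0.49 ± 0.20, adjusted p = 0.0918) did not pass. The most raised genes were Car3 (11.43 ± 1.2), the guanylate-binding protein Gbp10 (10.19 ± 0.76), the interferon-induced GTPase Tgtp2 (9.34 ± 0.61), Inmt (8.80 ± 1.01) and Upp2 (8.80 ± 1.01). Reg3b and Reg3g had no count in the STAT3KO libraries and were at least 38100-fold and 18060-fold lower, and Trat1 at least 793.5-fold lower. A2m was at -14.72 ± 1.70, and Igdcc4, with 3 counts left, had a ratio of 1708 (584.2 to 8287) in favour of the IL-6 group. Reads of close paralogs such as Tgtp1 and Tgtp2 or the Gsta genes may be split between members in counting, so single members of these families are uncertain.

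The interferon list had camera adjusted p = 3.37e-42 with the preset, with Irf7 (4.22 ± 0.28) and Gbp7 (4.64 ± 0.32) also higher. Acute phase genes had camera adjusted p = 9.06e-40 and adjusted p = 0.00932 with an estimated correlation. Cytochrome P450 and conjugation genes had 18 of 27 higher and 1 lower (21 and 1 when adjusted over the list alone), with Cyp2f2 (4.95 ± 0.36), Ugt2b1 (5.45 ± 0.41) and Fmo5 (3.27 ± 0.30). The cytochrome P450 list had camera adjusted p = 1.01e-15, and adjusted p = 0.197 with an estimated correlation. Bile acid genes had 14 of 19 higher (16 when adjusted over the list alone), with Slco1a1 (6.67 ± 0.48), Slco1a4 (5.25 ± 0.60) and Cyp7a1 (6.99 ± 0.99). The bile acid list had camera adjusted p = 7.68e-11, and adjusted p = 0.110 with an estimated correlation. Amino acid, urea and glucose genes had 17 of 26 higher (20 when adjusted over the list alone), with Slc2a2 at 5.63 ± 0.47. The amino acid list had camera adjusted p = 1.38e-11, and adjusted p = 0.248 with an estimated correlation. NRF2 targets had 17 of 23 higher and 2 lower (18 and 2 when adjusted over the list alone), with Gsta2 (8.66 ± 0.68), Gstm1 (5.80 ± 0.52), Gstm3 (8.05 ± 0.73) and Gsta1 (ratio 603.3, 206.1 to 2928). The NRF2 target list had camera adjusted p = 1.57e-12, and adjusted p = 0.197 with an estimated correlation.

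Progenitor and biliary genes had 9 of 16 lower and 1 higher in both ways of adjusting, with Tnfrsf12a (-3.61 ± 0.31), Spp1 (-8.05 ± 1.49) and Cd24a (-4.69 ± 1.03). The progenitor list had camera adjusted p = 0.000366, and adjusted p = 0.509 with an estimated correlation. IL-6 and STAT3 signalling had 11 of 27 lower and 1 higher (camera adjusted p = 0.000489, adjusted p = 0.227 with an estimated correlation). The unfolded protein response had 10 of 23 lower and 1 higher (12 and 1 when adjusted over the list alone), with Xbp1 (-2.20 ± 0.22), Pdia4 (-1.67 ± 0.25) and Dnajb11 (-1.28 ± 0.19). That response had camera adjusted p = 4.95e-05, and adjusted p = 0.328 with an estimated correlation. Immediate early genes had 6 of 17 lower and 2 higher (7 and 2 when adjusted over the list alone), with Ier3 (-7.20 ± 0.39), Junb (-1.56 ± 0.27) and Klf6 (-1.46 ± 0.28). The immediate early list had camera adjusted p = 0.000195, and adjusted p = 0.463 with an estimated correlation. Fatty acid oxidation had 6 of 23 higher and 2 lower (camera adjusted p = 0.0419, adjusted p = 0.838 with an estimated correlation). Dendritic cell markers had 3 of 7 higher, with H2-Ab1 (5.43 ± 0.88) and Irf8 (2.13 ± 0.37), which interferon also induces (camera adjusted p = 0.0122, adjusted p = 0.4 with an estimated correlation). Kupffer cell markers had 3 of 14 higher (adjusted p = 0.443) and general macrophage markers 1 of 12 (adjusted p = 0.272). Neutrophil markers had 3 of 6 lower (4 when adjusted over the list alone) and the median furthest from 0 of the marker lists, -3.22 (adjusted p = 0.0994). With a log2 fold change over 1 required as well, 2479 of the 3781 genes passed.

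The IL-6 STAT3KO hepatocytes were also compared with the GFP plasmid group, where interferon targets had the smallest camera p of all lists. Of 33 interferon targets, 28 were higher and none lower (32 and none when adjusted over the list alone), with a median of 3.65, and the list was called with the preset and with an estimated correlation (camera adjusted p = 1.19e-84 and adjusted p = 0.00932). Igtp was higher by 4.76 ± 0.38, the GTPase Irgm1 by 3.68 ± 0.31 and the interferon regulator Irf7 by 3.75 ± 0.33. Of 31 acute phase genes only Hpx passed (1.41 ± 0.32, adjusted p = 0.0326, and 0.0759 with no filter on low counts), and the list's median was 0.15 (adjusted p = 0.802).

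The test called 324 genes higher and 124 lower. Stat3 (0.07 ± 0.23, adjusted p = 0.903), Socs3 (-1.22 ± 0.34, adjusted p = 0.0771), Sox9 (1.14 ± 0.49, adjusted p = 0.233), Il6ra (-0.27 ± 0.47, adjusted p = 0.805), Il6st (-0.21 ± 0.22, adjusted p = 0.660) and Il6 (ratio 23.8, 4.03 to 964.3, adjusted p = 0.622) did not pass. The most raised genes were the ubiquitin-like Ubd (ratio 1799, 497.8 to 14860), Tgtp1 (9.49 ± 0.74), Tgtp2 (9.03 ± 0.72), Gbp8 (ratio 562.1, 192.1 to 2727) and Cd74, the invariant chain of MHC class II (7.26 ± 1.05, adjusted p = 0.00246). The most lowered were the urinary proteins Mup15 (ratio 2240, 619.4 to 18500, in favour of GFP), Mup14 (-6.80 ± 1.24) and Mup17 (-2.96 ± 0.67), the pseudogene Serpina4-ps1 (-5.10 ± 1.09) and Hsd3b5 (-3.10 ± 0.70), where paralogs of the Mup and Serpina families can share reads.

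NRF2 targets had 5 of 23 higher (12 when adjusted over the list alone), with the quinone reductase Nqo1 (2.49 ± 0.32), Gsta1 (5.36 ± 0.78), Gstm3 (4.15 ± 0.72) and Srxn1 (2.36 ± 0.45). The NRF2 target list had camera adjusted p = 2.34e-10, and adjusted p = 0.224 with an estimated correlation. Bile acid genes had 2 of 19 higher, the exporters Abcc4 (3.27 ± 0.39) and Abcb1a (3.54 ± 0.53), and 1 lower, Slco1a1 (-1.91 ± 0.40), with adjusted p = 0.422. IL-6 and STAT3 signalling had 2 of 27 higher (among them Socs1, 6.49 ± 0.69) and 2 lower (Junb, -1.78 ± 0.30, and Pim3, -1.83 ± 0.42), with adjusted p = 0.843. No member passed among 27 cytochrome P450 genes (adjusted p = 0.936), 26 amino acid genes (adjusted p = 0.853), 16 progenitor genes (adjusted p = 0.0518) or 20 hepatocyte transcription factors (adjusted p = 0.382). Immediate early genes had 2 of 17 lower (9 when adjusted over the list alone, camera adjusted p = 1.09e-05, adjusted p = 0.328 with an estimated correlation). Cell cycle genes had 1 of 32 higher (camera adjusted p = 5.1e-08, adjusted p = 0.612 with an estimated correlation) and YAP targets 1 of 16 higher (6 when adjusted over the list alone, camera adjusted p = 0.0173, adjusted p = 0.409 with an estimated correlation). The unfolded protein response had none of 23 past the threshold and a median of -0.35 (camera adjusted p = 0.0224, adjusted p = 0.612 with an estimated correlation). Dendritic cell markers had 2 of 7 higher, Irf8 (4.04 ± 0.49) and H2-Ab1 (5.72 ± 1.07). The dendritic cell list had camera adjusted p = 0.000186, and adjusted p = 0.207 with an estimated correlation. Kupffer cell markers had 1 of 14 higher, Il18bp (3.51 ± 0.47), and 8 when adjusted over the list alone. The Kupffer cell list had camera adjusted p = 1.36e-05, and adjusted p = 0.407 with an estimated correlation. General macrophage markers had none of 12 higher and 7 when adjusted over the list alone (camera adjusted p = 0.000399, adjusted p = 0.578 with an estimated correlation).

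The count of 448 genes was 910 with only these groups in the fit and 1146 with DESeq2. It fell to 90 without GFP replicate 1, 100 without GFP replicate 2, 257 without IL-6 STAT3KO replicate 2 and 249 without replicate 3.

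Hepatocytes of mice on DDC diet were compared with GFP plasmid hepatocytes, the hepatocytes with neither DDC diet nor IL-6 plasmid, to describe the response to the diet, although genotype, AAV vector and hydrodynamic injection differ with the diet. Progenitor and biliary genes rose, with 12 of 16 up and none down (14 and none when adjusted over the list alone) and a median of 4.56 as fitted, or 4.24 with a member absent from GFP set to its bound. Sox9 rose from 2.57 ± 0.62 to 30.5 ± 1.62 CPM (SD, n = 2 each, log2 fold change 3.56 ± 0.54, adjusted p = 0.00203), Tnfrsf12a by 3.72 ± 0.38, and the annexins Anxa2 and Anxa3 by 5.86 ± 0.79 and 4.32 ± 0.86. NRF2 targets rose too, with 13 of 23 up and none down (19 and none when adjusted over the list alone), led by Gsta1 (128 ± 0.249 against 0.964 ± 0.0959 CPM), Nqo1 (2.53 ± 0.33), Gstm3 (5.28 ± 0.78) and the antioxidant enzyme Srxn1 (3.23 ± 0.49). Amino acid, urea and glucose genes fell, with 16 of 26 down and none up (18 and none when adjusted over the list alone). None of these 3 lists was called with an estimated correlation (camera adjusted p = 0.224, 0.224 and 0.288).

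The edgeR test called 1486 genes higher and 1188 lower. Stat3 (0.34 ± 0.25, adjusted p = 0.358), Socs3 (1.01 ± 0.37, adjusted p = 0.0718, and 0.0419 by DESeq2), Il6ra (-0.72 ± 0.52, adjusted p = 0.344) and Il6st (0.29 ± 0.24, adjusted p = 0.424) did not pass, and Il6 was at or under the floor of 3 counts in both groups. The most raised genes were Ly6d (at least 1122-fold), the cornified envelope gene Sprr1a (at least 897.4-fold), Spp1 (7.65 ± 1.82, adjusted p = 0.0154), the calcium-binding S100a11 (7.20 ± 1.31) and Gsta1 (7.04 ± 0.84). Hsd3b5 was at least 3319-fold lower, and Serpina4-ps1 (-10.95 ± 1.78), Mup7 (-8.08 ± 2.02), Mup21 (-7.89 ± 1.56) and Mup14 (-5.95 ± 1.40) followed.

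Camera gave adjusted p = 1.02e-10 for the progenitor list and 3.26e-10 for the NRF2 list with the preset. The amino acid list had camera adjusted p = 1.08e-09, with Hgd (-1.41 ± 0.23), the glycine methyltransferase Gnmt (-2.51 ± 0.42), the tryptophan oxygenase Tdo2 (-1.94 ± 0.36) and Sds (-3.06 ± 0.59) lower. YAP targets had 6 of 16 higher (9 when adjusted over the list alone), with Crim1 (2.00 ± 0.27), Tead1 (2.06 ± 0.36), Ajuba (3.84 ± 0.74) and Tgfb2 (at least 40.2-fold). The YAP target list had camera adjusted p = 8.44e-06, and adjusted p = 0.167 with an estimated correlation. Cell cycle genes had 9 of 32 higher in both ways of adjusting, with Mcm6 (4.37 ± 0.79) and Mcm2 (3.09 ± 0.61). The cell cycle list had camera adjusted p = 5.2e-07, and adjusted p = 0.629 with an estimated correlation. Acute phase genes had 9 of 31 higher and 3 lower (11 and 3 when adjusted over the list alone), with the lipopolysaccharide co-receptor Cd14 (6.59 ± 0.80) and Steap4 (2.31 ± 0.36) up and Serpina3k (-2.62 ± 0.35) and Serpina3m (-1.47 ± 0.26) down (adjusted p = 0.0649). Bile acid genes split, with 5 of 19 higher and 6 lower (5 and 7 when adjusted over the list alone, adjusted p = 0.637). The exporters Abcb1a (6.15 ± 0.58) and Abcc4 (3.88 ± 0.41) rose and Slco1a1 (-4.76 ± 0.52) and Cyp7b1 (-3.29 ± 0.47) were lower. Haem and porphyrin metabolism had 2 of 18 higher and 1 lower (adjusted p = 0.805), the haem-degrading Hmox1 (3.41 ± 0.60) and the transporter Slc48a1 (1.25 ± 0.29) up and Cpox of haem synthesis (-1.59 ± 0.29) down. Interferon targets had 6 of 33 higher and 1 lower (7 and 1 when adjusted over the list alone, camera adjusted p = 0.0219, adjusted p = 0.704 with an estimated correlation). Among hepatocyte transcription factors 4 of 20 were lower (5 when adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.485 with an estimated correlation), and among cytochrome P450 genes 5 of 27 (adjusted p = 0.0715). The unfolded protein response had none of 23 past the threshold (adjusted p = 0.843).

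Markers of some other liver cells were higher with the diet, although none of these lists was called with an estimated correlation. Kupffer cell markers had 9 of 14 higher (10 when adjusted over the list alone), such as the scavenger receptor Marco (7.02 ± 1.31) and Cd5l (3.87 ± 0.84). The Kupffer cell list had camera adjusted p = 0.000182, and adjusted p = 0.485 with an estimated correlation. General macrophage markers had 9 of 12 higher and 1 lower (11 and 1 when adjusted over the list alone), with Cd68 (3.92 ± 0.77) and C1qb (3.41 ± 0.73). The general macrophage list had camera adjusted p = 0.000246, and adjusted p = 0.554 with an estimated correlation. Stellate cell markers had 2 of 13 higher, Lum (3.26 ± 0.84) and Pdgfrb (2.30 ± 0.63), and 11 when adjusted over the list alone. The stellate cell list had camera adjusted p = 0.000159, and adjusted p = 0.546 with an estimated correlation. Cholangiocyte markers had 3 of 7 higher (4 when adjusted over the list alone), with Bicc1 (5.91 ± 1.35) and Dsg2 (1.39 ± 0.29). The cholangiocyte list had camera adjusted p = 0.00456, and adjusted p = 0.302 with an estimated correlation. Dendritic cell markers had 3 of 7 higher (camera adjusted p = 0.0298, adjusted p = 0.485 with an estimated correlation). No member passed among markers of sinusoidal endothelial cells (median 0.41, adjusted p = 0.289), T cells (0.45, adjusted p = 0.805), B and plasma cells (-0.44, adjusted p = 0.879) or neutrophils (2.59 as fitted and 0.25 with absent members at their bound, adjusted p = 0.284). Hepatocyte markers had 5 of 17 lower and 1 higher (8 and 1 when adjusted over the list alone), with Serpina1c (-3.36 ± 0.39) and Mup3 (-4.93 ± 0.76). The hepatocyte marker list had camera adjusted p = 0.000363, and adjusted p = 0.4 with an estimated correlation. The count of 2674 genes was 4329 with only these groups in the fit, and it fell to 773 without GFP replicate 1, 632 without GFP replicate 2, 1244 without DDC replicate 1 and 742 without DDC replicate 2.

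The matched pair for STAT3 deletion is DDC STAT3KO against DDC, with AAV-TBG-Cre against AAV-TBG-GFP in floxed mice on the same diet. Here the edgeR test called 0 genes, with 803 genes at an unadjusted p under 0.05, and DESeq2 called 15 (4 higher and 11 lower). Stat3 stood at 68.5 ± 16.5 (SD, n = 3) against 131 ± 26.9 CPM (n = 2), a log2 fold change of -0.94 ± 0.22 (adjusted p = 0.853 by edgeR and 0.0184 by DESeq2). Saa1, serum amyloid A, had 1.99 ± 1.48 against 61.1 ± 53.9 CPM (-4.90 ± 0.71, adjusted p = 0.112 by edgeR and 4.63e-12 by DESeq2). The deletion was compared to see which part of the DDC response needs hepatocyte STAT3.

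Socs3 (-1.41 ± 0.33), Sox9 (-1.55 ± 0.42), Steap4 (-1.35 ± 0.31), the pyruvate kinase Pklr (1.16 ± 0.29) and Cyp4f14 (0.91 ± 0.29) had adjusted p = 0.853 in edgeR. Il6ra was at 0.42 ± 0.47 (adjusted p = 0.893) and Il6st at -0.34 ± 0.22 (adjusted p = 0.854), and Il6 was at or under the floor of 3 counts in both groups. The 15 genes of DESeq2, named after their values were seen apart from Stat3, Socs3, Saa1, Steap4, Pklr and Serpina1a, also held the acute phase genes Saa2 (-5.53, adjusted p = 0.0184), Lbp (-0.91, adjusted p = 0.0311) and Fgl1 (-3.18, adjusted p = 0.0467), and the complement genes C4b (-1.10, adjusted p = 6.13e-06) and Serping1 (-0.76, adjusted p = 0.0169). Of the 31 acute phase genes, 25 were below 0 in edgeR.

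Acute phase genes had a median of -0.72, none past the threshold and 6 lower when adjusted over the list alone (camera adjusted p = 1.73e-14, adjusted p = 0.110 with an estimated correlation). IL-6 and STAT3 signalling had a median of -0.22 and 5 of 27 lower when adjusted over the list alone (camera adjusted p = 0.000363, adjusted p = 0.224 with an estimated correlation). The median was -0.87 for the 16 progenitor and biliary genes (camera adjusted p = 0.000363, adjusted p = 0.495 with an estimated correlation) and -0.60 for the 16 YAP targets (camera adjusted p = 0.000692, adjusted p = 0.224 with an estimated correlation). It was 0.46 for the 26 amino acid genes (camera adjusted p = 9.58e-06, adjusted p = 0.485 with an estimated correlation) and 0.39 for the 27 cytochrome P450 genes (camera adjusted p = 0.0242, adjusted p = 0.704 with an estimated correlation). For interferon targets it was -0.04, with a mean of 0.03 (adjusted p = 0.843). Markers of stellate cells (median -0.76, camera adjusted p = 0.000489, adjusted p = 0.581 with an estimated correlation), cholangiocytes (-0.92, camera adjusted p = 0.00243, adjusted p = 0.248 with an estimated correlation) and macrophages (-0.44, camera adjusted p = 0.00466, adjusted p = 0.663 with an estimated correlation) were also below 0, with no member past the threshold. Hepatocyte markers had a median of 0.39 (camera adjusted p = 0.00713, adjusted p = 0.545 with an estimated correlation). DDC STAT3KO replicate 1 had 2.03% mitochondrial counts, against 5.38% and 5.26% in the other replicates and 5.48% and 5.21% in the DDC libraries. DDC STAT3KO replicate 3 stood apart from the other replicates of its group, with 2.32 CPM of Spp1 against 244.2 and 226.0, and 11.4 CPM of Clec4f, a Kupffer cell gene, against 80.7 and 80.9. Without DDC replicate 1 or replicate 2, the edgeR test called 1 gene.

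Whether STAT3KO hepatocytes differed from their control by another amount with the IL-6 plasmid than with DDC diet was tested as an interaction, where a positive value means a larger log2 fold change in the IL-6 pair. In that pair genotype, AAV vector and Il6 level differ as well, so the term is not a test of STAT3 deletion alone. Acute phase genes had 22 of 31 lower and none higher (28 and none when adjusted over the list alone, median -2.94), with Itih3 (-3.48 ± 0.41), Serpina3n (-2.76 ± 0.34), Fgb (-2.83 ± 0.41) and Hp (-3.30 ± 0.49). Interferon targets had 25 of 33 higher and none lower (32 and none when adjusted over the list alone, median 3.32), with Igtp (4.90 ± 0.42), Irf7 (4.26 ± 0.38), Gbp7 (4.68 ± 0.43) and Ifi44 (6.54 ± 0.64). Both calls held with an estimated correlation (camera adjusted p = 1.78e-30 and 7.37e-51, adjusted p = 0.00932 and 0.0326 with an estimated correlation). The interaction term passed for 602 genes higher and 585 lower, including Socs3 (-4.26 ± 0.48, adjusted p = 0.000342) and Sox9 (-2.45 ± 0.59, adjusted p = 0.0261, and 0.12 without DDC replicate 2). It did not pass for Stat3 (-0.83 ± 0.31, adjusted p = 0.119), Il6ra (-0.09 ± 0.63, adjusted p = 0.954) or Il6st (-0.15 ± 0.30, adjusted p = 0.816), and for Il6 it is not given because the DDC groups were at the floor.

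The most positive genes were Gbp10 (10.23 ± 0.94), Car3 (9.46 ± 1.32), Tgtp2 (9.27 ± 0.89), Gsta1 (8.79 ± 1.10) and Gsta2 (8.54 ± 0.81). The most negative were A2m (-13.45 ± 3.80, adjusted p = 0.0493, and 0.0634 with only these groups in the fit), Rtn4rl2 (-9.98 ± 1.02), Igdcc4 (-9.14 ± 1.41), Obp2a (-7.23 ± 1.51) and Cyp17a1 (-7.09 ± 1.28). Bile acid genes had 10 of 19 higher (14 when adjusted over the list alone, camera adjusted p = 5.67e-14, adjusted p = 0.0606 with an estimated correlation). In the same contrast, 14 of 27 cytochrome P450 genes were higher and 1 lower (camera adjusted p = 2.8e-15, adjusted p = 0.197 with an estimated correlation). NRF2 targets had 12 of 23 higher (camera adjusted p = 4.79e-16, adjusted p = 0.158 with an estimated correlation). Of 26 amino acid genes, 7 were higher (camera adjusted p = 7.35e-07, adjusted p = 0.407 with an estimated correlation), and of 23 unfolded protein response genes 8 were lower (camera adjusted p = 1.32e-06, adjusted p = 0.224 with an estimated correlation). The count of 1187 genes was 1881 with DESeq2, 1377 without IL-6 replicate 3, 1608 without DDC STAT3KO replicate 3 and 2151 without both, a choice made after seeing the data. It was 686 without IL-6 replicate 2, 723 without IL-6 STAT3KO replicate 3, 622 without DDC replicate 1 and 477 without DDC replicate 2.

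The responses to IL-6 and to DDC were set against each other across genes. Of the genes tested, 799 were higher and 734 lower in both, where independent lists would share 203.5 and 145.4, while 13 genes were higher with IL-6 and lower with DDC and 11 the reverse, where independent lists would share 162.7 and 181.9. The log2 fold changes had r = 0.676 across genes, against a mean of 0.576 in 20 simulations of unchanged groups that share the GFP libraries, and a covariance of 1.99 against 0.295. With 1 GFP library as the control for IL-6 and the other for DDC, so that no library is shared, r was 0.586 and 0.590 in the 2 ways of doing so, a choice made after seeing the data. Of the 1964 genes higher with IL-6, 1243 (63.3%) were lower in IL-6 STAT3KO than in IL-6, and of the 1755 lower genes 1156 (65.9%) were higher. These contrasts share the IL-6 libraries (r = -0.749, simulated mean -0.445).

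The pairs without a shared library were tested as gene sets. The 1577 genes raised more than 2-fold by IL-6 had a median log2 fold change of -0.31 in DDC STAT3KO against DDC, where all genes had 0.01. Of the set, 1159 (73.5%) lay below 0, none passed the gene test, and camera gave p = 1.71e-14, with p = 0.0446 with an estimated correlation. With an estimated correlation this did not hold in several settings, with p = 0.1503 with the replicate block, 0.0772 without IL-6 replicate 3, 0.0957 without DDC replicate 1 and 0.0742 without DDC replicate 2. Leaving out DDC STAT3KO replicate 3 alone gave a median of -0.13 and camera p = 0.268 with an estimated correlation. Without both it and IL-6 replicate 3, chosen after seeing the data, the median was -0.11, with camera p = 0.389 with an estimated correlation. The 1281 genes raised more than 2-fold by DDC had a median of -0.42 in IL-6 STAT3KO against IL-6, with 381 lower and 97 higher, 816 (63.7%) below 0, and camera p = 7.47e-07, with p = 0.278 with an estimated correlation (0.0324 to 0.401 with each library left out). The STAT3KO differences with IL-6 and with DDC had r = 0.202 across genes. It was 0.315 over genes with a mean of at least 20 CPM, 0.121 with no filter and 0.130 without DDC STAT3KO replicate 3. Without that library and IL-6 replicate 3, again chosen after seeing the data, it was 0.0988.

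Liver macrophages of mice on DDC diet were compared with those on normal diet, to see which signals injury raises in them. Of 13 genes of lipid-associated macrophages, a state seen in damaged tissue, 3 were higher over all genes and 10 when adjusted over the list alone, with none lower and a median of 2.48. The list was called with the preset correlation but not with an estimated one (camera adjusted p = 1.36e-19 and 0.119). Cd63, a tetraspanin of lysosomes, rose from 5.49 ± 1.60 to 509 ± 25.3 CPM (SD, n = 2 each, 6.53 ± 0.61, adjusted p = 0.000134), the tetraspanin Cd9 by 4.51 ± 0.66 (adjusted p = 0.0258) and the macrophage elastase Mmp12 by 3.98 ± 0.62 (adjusted p = 0.0322). Without DDC replicate 1, Cd9 (adjusted p = 0.152) and Mmp12 (adjusted p = 0.263) did not pass. Il6 did not pass, at 4.56 and 18.1 CPM on DDC and 6.14 and 13.1 CPM on normal diet (0.24 ± 1.44, adjusted p = 0.955), and neither did any other of the 7 measured gp130 cytokines. Osm was at 1.99 ± 1.08 and Clcf1 at 3.09 ± 1.55 (adjusted p = 0.460 for both), Ctf1 at 1.98 ± 2.65, Il27 at -0.35 ± 1.66, Il11 at -3.41 ± 2.71 and Lif at -3.04 ± 2.61.

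The edgeR test called 7 genes, all higher. The other 4 were Gstm3 (7.85 ± 1.15), the keratin Krt8 (7.15 ± 1.14), Mup20 (6.29 ± 0.94) and Gstm1 (5.06 ± 0.81), which hepatocytes express strongly, with adjusted p of 0.0258 to 0.0345. These 4 differed between the DDC replicates as hepatocyte markers did: replicate 1 held 2439 CPM of Gstm3 and replicate 2 339.4 CPM, and Alb stood at 913.9 and 108.7 CPM. Cell cycle genes had a median of 1.37 with none of 32 past the threshold, a call that held with an estimated correlation (camera adjusted p = 1.73e-08, adjusted p = 0.0213). Markers of sinusoidal endothelial cells had a median of -1.70 and 8 of 12 lower when adjusted over the list alone, with Kdr at -3.35 ± 0.64 (camera adjusted p = 1.41e-06, adjusted p = 0.367 with an estimated correlation). Hepatocyte markers had 1 of 17 higher and 8 when adjusted over the list alone (median 2.08, camera adjusted p = 4.92e-06, adjusted p = 0.395 with an estimated correlation). Kupffer cell markers had none of 14 past the threshold and 3 when adjusted over the list alone, with Marco at 4.07 ± 0.89 (camera adjusted p = 4.92e-06, adjusted p = 0.334 with an estimated correlation). The unfolded protein response had 9 of 23 higher when adjusted over the list alone, with Sdf2l1 at 2.19 ± 0.56 (camera adjusted p = 6.68e-08, adjusted p = 0.293 with an estimated correlation), and haem and iron handling 5 of 14 (camera adjusted p = 4.69e-07, adjusted p = 0.243 with an estimated correlation). MHC class II presentation (13 measured, median 0.79, camera adjusted p = 6.62e-05), inflammatory cytokines (22 measured, median 0.88, camera adjusted p = 0.000209), NF-kB feedback (15 measured, median 0.94, camera adjusted p = 0.00498) and patrolling monocyte genes (13 measured, median 0.69, camera adjusted p = 0.00211) had no member past the threshold, and adjusted p = 0.347, 0.381, 0.385 and 0.381 with an estimated correlation. These medians lay near the 0.77 of genes of at least 20 CPM. Growth factors and other hepatocyte ligands had none of 18 past the threshold, with Bmp2 at -3.07 ± 0.66 and Igf1 at 1.70 ± 0.45 (adjusted p = 0.477 for the list).

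Scaling moved the median of all genes, from -0.62 with TMM to -1.12 with median-of-ratios factors. The 7 genes became 17 with median-of-ratios factors (11 higher, 6 lower), 26 with the replicate block and 240 with no filter. They became 1661 with only these groups in the fit and 660 with DESeq2 (203 higher, 457 lower). The count was 1 without DDC macrophage replicate 1, 15 without replicate 2 and 13 without normal diet replicate 1, and the 2935 genes at an unadjusted p under 0.05 show how few pass the correction.

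Macrophages of DDC livers were then compared with the mean of the other sorted immune cells, to see which ligands they express above other cells. Kupffer cell genes set them apart, with 13 of 14 higher and none lower (14 and none when adjusted over the list alone, median 4.03). Clec4f, a lectin of Kupffer cells, stood at 9609 and 8138 CPM, against 72.8 to 146.4 CPM in monocytes (4.76 ± 0.35, adjusted p = 2.3e-06), and Vsig4 (4.30 ± 0.34), Cd5l (4.57 ± 0.40) and C6 (4.02 ± 0.35) were higher as well. Il6 was higher in macrophages, at 4.56 and 18.1 CPM against 0 to 2.94 CPM in the other cells (4.87 ± 1.08, adjusted p = 0.0485), the only one of 7 gp130 cytokines to pass. That call did not hold with median-of-ratios factors (adjusted p = 0.0762), with the replicate block (adjusted p = 0.0798), with only these groups in the fit (adjusted p = 0.0933) or without macrophage replicate 1 (adjusted p = 0.178) or replicate 2 (adjusted p = 0.897), and DESeq2 gave adjusted p = 0.00198. Osm, a cytokine of the same family, was at 12.5 and 22.4 CPM in macrophages and at 204.1 and 94.5 CPM in neutrophils (-1.61 ± 0.92, adjusted p = 0.723). Il27 (2.87 ± 1.13, adjusted p = 0.505), Ctf1 (4.48 ± 1.75, adjusted p = 0.506), Clcf1 (0.25 ± 1.10), Lif (-2.89 ± 2.36) and Il11 (-0.15 ± 2.46) did not pass.

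The edgeR test called 157 genes higher and 36 lower. Beside Kupffer cell genes, the most raised were the B cell chemokine Cxcl13 (5.34 ± 0.85), the lectins Cd209g (5.17 ± 0.42) and Cd209f (4.70 ± 0.45) and the folate receptor Folr2 (4.97 ± 0.53). The most lowered were Chil3 (-6.80 ± 1.14), Cyp4f18 (-6.20 ± 0.69), the leukotriene enzyme Alox5 (-5.65 ± 1.03), Nfe2 (-5.56 ± 1.11) and the decoy receptor Il1r2 (-5.49 ± 0.87). Growth factors and other hepatocyte ligands had 3 of 18 higher, Igf1 (2.79 ± 0.30, adjusted p = 5.82e-05), the granulin Grn (2.00 ± 0.37) and Hbegf (3.42 ± 0.66), with adjusted p = 0.0595 for the list. Grn and Hbegf did not pass without macrophage replicate 1 (adjusted p = 0.257 and 0.114). Haem and iron handling had 6 of 14 higher (10 higher and 1 lower when adjusted over the list alone), with the iron exporter Slc40a1 (3.55 ± 0.32), the haemoglobin receptor Cd163 (4.02 ± 0.44) and Blvrb (2.66 ± 0.38). The haem and iron list had camera adjusted p = 1.31e-16, and adjusted p = 0.0953 with an estimated correlation. General macrophage markers had 5 of 12 higher (10 when adjusted over the list alone), such as the complement genes C1qa (3.59 ± 0.38) and C1qc (3.38 ± 0.37). The general macrophage list had camera adjusted p = 1.04e-20, and adjusted p = 0.114 with an estimated correlation. Lipid-associated macrophage genes had 3 of 13 higher (5 when adjusted over the list alone), Mmp12 (2.68 ± 0.38), Lpl (2.58 ± 0.41) and Apoe (2.40 ± 0.43). The lipid-associated list had camera adjusted p = 7.53e-06, and adjusted p = 0.367 with an estimated correlation.

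Classical monocyte genes had 5 of 12 lower (8 when adjusted over the list alone, camera adjusted p = 6.47e-15) and neutrophil markers 3 of 14 lower (7 when adjusted over the list alone, camera adjusted p = 2.64e-08), each with adjusted p = 0.119 with an estimated correlation. Kupffer cell markers (camera adjusted p = 3.7e-64) and cell cycle genes (median 1.45, none of 32 past the threshold, camera adjusted p = 5.01e-09) held with an estimated correlation (adjusted p = 0.0213 for both). Inflammatory cytokines had 1 of 22 lower, Ptgs2 (-3.11 ± 0.59), and 5 higher and 1 lower when adjusted over the list alone (adjusted p = 0.124). Patrolling monocyte genes had 1 of 13 higher and 1 lower (adjusted p = 0.681). NK cell (10 measured, camera adjusted p = 0.00249), B cell (11 measured, camera adjusted p = 0.00454), T cell (16 measured, camera adjusted p = 0.0398) and erythroid markers (7 measured, camera adjusted p = 0.00596) had medians above 0 with no member past the threshold, and adjusted p = 0.269, 0.334, 0.367 and 0.381 with an estimated correlation. Cholangiocyte markers (12 measured, adjusted p = 0.431), MHC class II presentation (13 measured, adjusted p = 0.562), NF-kB feedback (15 measured, adjusted p = 0.0737) and the unfolded protein response (23 measured, adjusted p = 0.431) had neither a member past the threshold nor a call.

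Pair by pair, Il6 did not pass in macrophages against T cells (4.62, adjusted p = 0.474), neutrophils (9.78 as fitted, adjusted p = 0.0675), Ly6C-low (2.33, adjusted p = 0.916) or Ly6C-high monocytes (2.74, adjusted p = 0.996). Igf1 was higher than in neutrophils (3.24, adjusted p = 0.00207), Ly6C-low (2.92, adjusted p = 0.00733) and Ly6C-high monocytes (adjusted p = 0.000467) and did not pass against T cells (1.01, adjusted p = 0.525). Grn passed only against neutrophils (adjusted p = 0.0134), and Hbegf in no pair (adjusted p = 0.517, 0.352, 0.237 and 0.101 in the same order as Il6). Of the other ligands, named after their values were seen apart from Ptgs2, Il1a was higher than in both monocyte groups (adjusted p = 0.0289 and 0.0287), and Il1b, Il1rn, Bmp2 and Ptgs2 were lower than in neutrophils (adjusted p of 0.0429 or less). The edgeR test called 312 genes against neutrophils, 66 against Ly6C-low monocytes and 146 against Ly6C-high monocytes. Against T cells it called 0, with 2601 genes at an unadjusted p under 0.05. The libraries labelled T cell held 1639 and 2513 CPM of Clec4f, 90.0 and 68.1 CPM of the T cell receptor chain Cd3g, against 18.5 and 8.58 CPM of Cd3g in DDC macrophages, and 2102 and 1112 CPM of Alb.

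The count of 193 genes (81.3% higher) was 231 with median-of-ratios factors (64.9% higher), which moved the median of all genes from -0.01 to -0.24. It was 470 with no filter, 696 with DESeq2 (303 higher, 393 lower) and 390 without the T cell libraries, a choice made after seeing the data. Left out in turn, single libraries gave 61 (macrophage replicate 1), 70 (macrophage replicate 2), 469 (T cell replicate 2), 1059 (neutrophil replicate 1), 352 (neutrophil replicate 2) and 124 genes (Ly6C-low replicate 1).

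**Figure D3:**
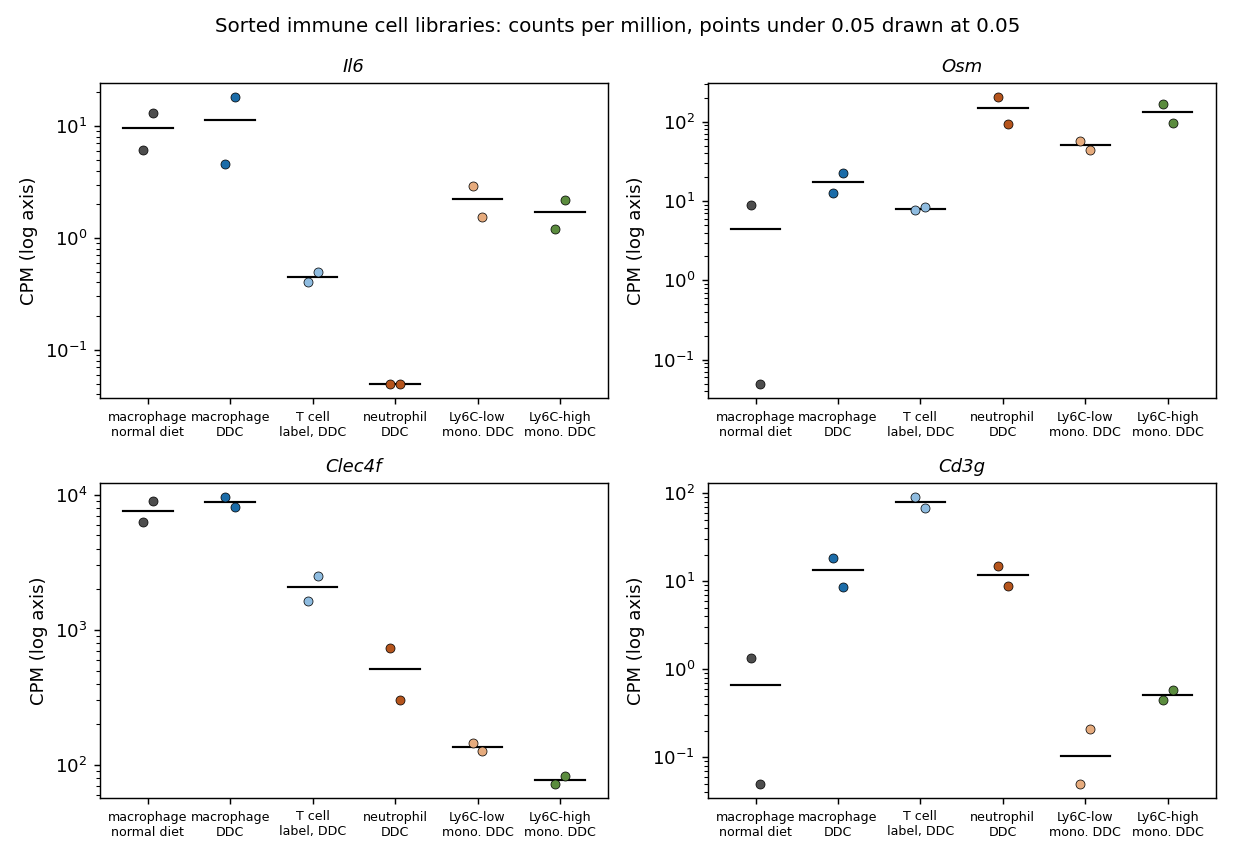
CPM (log axis) of Il6, Osm, Clec4f and Cd3g in each sorted immune cell library by group, with the group mean as a line and points under 0.05 CPM drawn at 0.05. Il6 was highest in the macrophage groups (4.56 to 18.1 CPM), Osm in neutrophils and Ly6C-high monocytes (94.5 to 204.1 CPM), and Cd3g in the T cell libraries (68.1 and 90.0 CPM).

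The sorted monocyte populations of DDC livers were compared with each other. Classical monocyte genes were at higher levels in Ly6C-high cells, with a median of 2.17 and 8 of 12 higher when adjusted over the list alone, although none passed over all genes and the list was not called with an estimated correlation (camera adjusted p = 0.114). Among them Chil3 was at 6.17 ± 1.13 (adjusted p = 0.364). The Ly6C-low libraries held more hepatocyte transcripts, with Mup20 at 96.5 ± 55.6 against 8.26 ± 4.07 CPM (SD, n = 2 each) and 12 of 17 hepatocyte markers lower in Ly6C-high cells when adjusted over the list alone (median -2.66). The edgeR test called 0 genes, with 461 at an unadjusted p under 0.05, and DESeq2 called 36 (12 higher, 24 lower). Among gp130 cytokines Osm was at 1.38 ± 1.05, Il6 at -0.41 ± 1.46 and the others did not pass either.

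Camera gave adjusted p = 2.97e-18 for classical monocyte genes and 2.51e-27 for hepatocyte markers, with adjusted p = 0.114 and 0.119 with an estimated correlation. Cell cycle genes had a median of -0.97, a call that held with an estimated correlation (camera adjusted p = 4.26e-08, adjusted p = 0.0213). Neutrophil markers had 3 of 14 higher and 8 lower when adjusted over the list alone, and a median of -2.74, or -2.11 with members absent from a group set to their bound (camera adjusted p = 0.000247, adjusted p = 0.290 with an estimated correlation). Markers of sinusoidal endothelial cells had a median of 1.41 and 5 of 12 higher when adjusted over the list alone (camera adjusted p = 7.53e-06, adjusted p = 0.380 with an estimated correlation). Dendritic cell markers had a median of -1.66 and 1 of 10 lower when adjusted over the list alone (camera adjusted p = 0.000909, adjusted p = 0.334 with an estimated correlation), and Kupffer cell markers a median of -0.80 (camera adjusted p = 3.37e-07, adjusted p = 0.293 with an estimated correlation). Patrolling monocyte genes had a median of 0.28 (adjusted p = 0.477). The count of 0 became 1 with median-of-ratios factors, 2 with the replicate block, 74 with no filter and 197 with only these groups in the fit.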

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

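The split test, the interaction test and camera with an estimated correlation were set before the data were examined, and all other tests named in this part were chosen only after the result was seen.

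The difference of STAT3KO hepatocytes from their control was not the same with the IL-6 plasmid and with DDC diet by the interaction test in 1187 genes, with a median interaction of -2.94 for acute phase genes and 3.32 for interferon targets. In the IL-6 pair genotype, vector and Il6 level differ too, so this is not assigned to STAT3 deletion. EGFP reads, which lie outside the measured genes, stood at 1186 and 1229 CPM in the DDC libraries, where AAV-TBG-GFP was given, and at 9.24, 5.73 and 486.3 CPM in the IL-6 libraries, whose labels name no GFP. The libraries labelled with a GFP plasmid held 2.18 and 2.41 CPM, less than any IL-6 library. They held more than the STAT3KO libraries, which had 0.559 to 1.34 CPM with IL-6 and 0 to 0.0484 CPM with DDC. These reads therefore neither establish nor exclude the GFP plasmid label, and the cause was not tested.

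The acute phase part of the IL-6 response was missing in IL-6 STAT3KO hepatocytes, where acute phase genes had a mean log2 CPM of 7.49 ± 0.25 (SD, n = 3) against 11.71 ± 0.14 (n = 3) with IL-6 and 7.34 ± 0.24 (n = 2) with the GFP plasmid. Lower plasmid expression may explain it, since the lowest IL-6 library held 3.05 times the Il6 CPM of the highest IL-6 STAT3KO library. Against that, the acute phase mean differed by only 0.27 among IL-6 libraries whose Il6 level ran from 3.21 to 350.9 CPM. Deletion of STAT3 may explain it too, and in the matched DDC pair the acute phase median was -0.72, with adjusted p = 0.110 by camera with an estimated correlation. Both explanations stay open.

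Interferon targets were higher in IL-6 STAT3KO hepatocytes than in any other hepatocyte group. AAV-Cre and the floxed genotype by themselves could be the source, but the DDC STAT3KO libraries share them and the gap between the lowest IL-6 STAT3KO and the highest DDC STAT3KO library was 2.29 log2 units, which argues against this. More macrophage RNA could be the source, but macrophage markers had a median of 0.37 against IL-6, where the lower quartile of interferon targets was 2.06, which argues against it as well. AAV-Cre or the floxed genotype together with hydrodynamic injection stays open, as no group shows that combination without IL-6.

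Kupffer cell transcripts were present in the libraries labelled T cell. Macrophage RNA could be the source, as Kupffer cell markers moved together. Their log2 ratio to DDC macrophages had an SD of 0.367, where normal diet against DDC macrophages had 1.03. The lower T cell library held 2.69 times the summed T cell marker CPM of the highest other library, which argues against a swapped label. That leaves a mixed sort open, as no other group was of T cells.

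In IL-6 STAT3KO against IL-6, 1 of 10 splits of the libraries, the real one, called 3781 genes and the highest other split called 1, and 10 splits are too few for a share under 0.05.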

How the results depend on the processing

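The limits of the design apply to every result: groups of 2 or 3 libraries, replicates not stated to be separate animals, genotype and AAV vector that differ together in IL-6 STAT3KO against IL-6 and against GFP, and genotype, vector, injection and diet that differ together in DDC against GFP. The cause of the differences between settings was not tested. No named gene that passed in the main test or in the alternative reversed its direction.

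The balance of higher and lower calls did turn in some settings. IL-6 against GFP had 1964 higher and 1755 lower, but 837 and 940 without GFP replicate 1 and 788 and 914 without GFP replicate 2. DDC against GFP had 1486 higher and 1188 lower, but 375 and 398 without GFP replicate 1. IL-6 STAT3KO against IL-6 had 1866 higher and 1915 lower, but 1917 and 1914 with the replicate block, 1841 and 1757 without IL-6 replicate 3, and 1295 and 1264 without IL-6 STAT3KO replicate 3. Without IL-6 replicate 3 and DDC STAT3KO replicate 3, a choice made after seeing the data, it had 2274 and 2148. The interaction had 602 higher and 585 lower, but 880 and 1001 with DESeq2 and 531 and 541 without IL-6 STAT3KO replicate 2. With DESeq2, DDC against normal macrophages turned from 7 higher and 0 lower to 203 and 457, and macrophages against other cells from 157 and 36 to 303 and 393.

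Counts of called genes changed with the setting. With a log2 fold change over 1, IL-6 STAT3KO against IL-6 had 2479 genes. With median-of-ratios factors, DDC against normal macrophages had 17 and the monocyte comparison 1. With no filter on low counts these had 240 and 74, and macrophages against other cells 470. With only the compared groups in the fit, IL-6 STAT3KO against GFP had 910, DDC against GFP 4329, DDC against normal macrophages 1661 and the monocyte comparison 197. With DESeq2 the counts were 1146 for IL-6 STAT3KO against GFP, 15 for DDC STAT3KO against DDC, 1881 for the interaction, 660 for DDC against normal macrophages, 696 for macrophages against other cells and 36 for the monocytes. Among settings chosen after seeing the data, leaving out IL-6 replicate 3 and DDC STAT3KO replicate 3 gave 2151 genes for the interaction, and leaving out the T cell libraries gave 390 for macrophages against other cells.

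With each library left out in turn, the counts ran from 1702 to 3472 for IL-6 against GFP, 90 to 433 for IL-6 STAT3KO against GFP, 632 to 1244 for DDC against GFP, 0 to 1 for DDC STAT3KO against DDC, 477 to 1608 for the interaction, 1 to 15 for DDC against normal macrophages and 61 to 1059 for macrophages against other cells.

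The correlation of the IL-6 and DDC responses was 0.607 over genes of at least 20 CPM, 0.647 with no filter, 0.651 without IL-6 replicate 3 and DDC STAT3KO replicate 3, and 0.635 to 0.724 with each library left out. With 1 GFP library for each contrast, chosen after seeing the data, it was 0.586 and 0.590. The STAT3KO differences had r = 0.315 over genes of at least 20 CPM, 0.121 with no filter and 0.0988 without both libraries. It was 0.130 to 0.225 with each library left out.

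With the replicate number as a block, DDC against normal macrophages had 26 genes and the monocyte comparison 2. The STAT3KO differences had r = 0.153. Fatty acid oxidation in DDC STAT3KO against DDC, not called without the block, was called lower with it, opposite to its direction without it (camera adjusted p = 0.0278). Whether the numbers pair libraries is not settled. After removing group means, libraries of the same number in IL-6 and IL-6 STAT3KO had r = -0.150 to 0.0922, and 1 of 3 matched its own number best. In IL-6 and DDC STAT3KO they had r = 0.0609, 0.138 and 0.191, and in IL-6 STAT3KO and DDC STAT3KO -0.159, 0.318 and 0.0446.

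Of the list calls, 5 hepatocyte and 4 immune calls held with an estimated correlation, while fry called 48 and 7, of which 3 hepatocyte calls were not among the list calls.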

Other observations

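The gene for the erythroid form of aminolevulinate synthase, Alas2, was lower in hepatocytes with IL-6 than with the GFP plasmid (-4.96 ± 0.35, adjusted p = 8.12e-06 by edgeR) and lower with DDC (-3.03 ± 0.38). Its value was chosen after it was seen.

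The neutrophil libraries held 729.0 and 301.5 CPM of Clec4f, a Kupffer cell gene, beside 15480 and 6563 CPM of the neutrophil gene S100a8, where Ly6C-high monocytes held 72.8 and 83.0 CPM of Clec4f. The source of these reads was not tested.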
